A study of Mus musculus with 8 samples.

How the data were processed

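RNA was sequenced from T cells of 14-week-old MRL/lpr mice, a strain that carries the lpr mutation of the Fas gene and develops a lupus-like disease with kidney inflammation. CD4+ and CD8+ T cells with high surface CD44, a protein that marks cells that have met antigen, were sorted from kidney and from spleen, per the labels. The 2 organs and 2 cell types gave 4 groups of 2 libraries, 8 libraries in all. RNA was isolated with a micro-scale column kit and libraries were made with the SMART-Seq v4 kit, which amplifies full-length complementary DNA from very small amounts of RNA and keeps no strand information.

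Reads were aligned to the mouse genome build mm9, per the labels. STAR 2.5.3 and TopHat2 2.1.0 are named in the submitters' processing notes, and the series text names STAR and Bowtie. Which aligner gave the values, the counting tool and the gene annotation are not given in the sources used here. The authors deposited 1 table of normalised signal per gene and library, with 13341 gene symbols and 8 columns, all of which were used, and 0 columns were left unused. The deposited signal values were whole multiples of a step that was the same for every gene of a library, so each value was a read count divided by 1 size factor per library. Dividing by that step gave whole reads for 100% of the values in each library (tolerance 1e-06). The recovered totals ranged from 7477544 to 11169003 reads per library. The size factors behind the deposited signal were 1.09 to 1.36 times the median-of-ratios factors recomputed from the same genes, so the table alone did not give the authors' factors back. A level below means the deposited normalised signal, and 1 read was worth 0.554 to 1.04 of it, depending on the library.

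Symbols were matched to a gene annotation of the same mm9 build for positions, transcript lengths and strands. Of the 13341 symbols 12069 were found, and 89.4% of the genes tested had a transcript length. Values of genes that share reads with a close copy, such as the globin genes or the killer lectin-like receptor genes, are uncertain because the counting is not described. In all, 282 genes that had reads held the same values in every library as another gene, Hbb-b2 and Hbb-bt among them. Genes that overlap on opposite strands could not be told apart either.

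Groups were compared on log2(level + 1) with limma 3.58.1 in R 4.3.3 (cell means of the 4 groups over all 8 libraries, empirical Bayes with an intensity trend, 2-sided). The 4 residual degrees of freedom became 8.48 with those borrowed across genes. Genes with a level of at least 10 in at least 2 libraries were tested, 10845 in number. Benjamini-Hochberg adjustment ran over these genes within each of 5 comparisons, and a gene was called at an adjusted p below 0.05. Fold changes are on the log2(level + 1) scale, which understates the change of genes with low levels, and are given with their standard error (SE). A fold against a group with 0 reads is a lower bound, taken against 3 reads over both libraries of that group together. With 1 to 3 reads, the ratio of reads is given with its 95% exact counting interval. Such bounds and intervals cover counting error only, because reads amplified without molecular identifiers are not independent molecules. Adjusted p-values in the text are from limma unless another tool is named.

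Gene lists for T cell states, metabolism, stress and other cell types, 38 in number, were tested with camera of limma at a preset correlation between genes of 0.01, for the 33 lists with at least 5 tested genes. Benjamini-Hochberg adjustment ran over the lists within a comparison. Beside each call stands the adjusted p with a correlation estimated for the list, and for members also the count of calls adjusted over the list alone. The lists of markers of other cells were chosen for kidney and spleen, and the natural killer cell and dendritic cell lists hold genes that T cells also express. The directions of the median, the mean and the test differed for 5 lists in the CD4+ organ comparison, 3 in the CD8+ one, 3 for the difference between them, 2 between cell types in kidney and 8 in spleen. None of these lists was called.

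Named genes followed a rule. It took up to 8 genes with the largest rise and up to 8 with the largest fall per comparison, among called genes whose groups did not overlap and whose level averaged at least 100 in the higher group. It also took up to 4 members with the smallest adjusted p per list described, and a fixed set that included Cd4, Cd8a, Foxp3, Pdcd1, Ifng, Gzmb, Tcf7 and Cxcr6. Gene models named only by a number, receptor segments and histone genes were left out of the first part. Values of some genes that the rule names are not reported here. The groups, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined.

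The tests were run on simulated data first. Reads were drawn from the means and depths of the real libraries, with 67 genes changed 2-fold, 67 changed 4-fold and 66 changed 16-fold, and the step ran on 10395 to 10429 genes. The 2-fold, 4-fold and 16-fold changes were given only to genes with a mean level of at least 50. A single data set was drawn per comparison. Other genes of the tissue residency list were also raised 2-fold. Each gene had the same spread in every group. That spread was estimated over all 4 groups, so it includes the kidney CD4+ pair and may be too wide for the others. The real kidney CD4+ replicates were less alike than those of other groups, so the simulated values may not hold for comparisons with them. Recovery is given with each comparison.

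Alternatives were another pseudocount (0.5 or 5), no filter or a stricter one (at least 50), other scalings (TMM, median of ratios, quantile), a fit of the compared libraries alone, robust empirical Bayes, the replicate number as a block, a 2-fold minimum, and each library left out in turn. The recovered reads were tested with the quasi-likelihood test of edgeR 4.0.16 and the Wald test of DESeq2 1.42.0, and lists also with an estimated correlation and with fry. Library weights, removal of each library's trend on transcript length, and the hypoxia list without members near 0 in spleen were added after the data were seen. The last of these can only remove rises, so it is left out of every count of alternatives. On the recovered reads, edgeR called 55 genes higher and 11 lower in kidney CD4+ cells, and 74 higher and 25 lower in kidney CD8+ cells. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

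The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. With 2 replicate numbers, numbers alone did not show that samples were paired, and the main model has no block.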

Results

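Antigen-experienced CD4+ and CD8+ T cells of MRL/lpr lupus mice were compared between the inflamed kidney and the spleen, to ask how T cells in the target organ differ from those in a lymphoid organ. Each of the 4 groups had 2 libraries (n = 2 throughout). Depth was 8880902 and 7483737 reads for kidney CD4+ cells and 9215384 and 9707761 for kidney CD8+ cells. It was 11169003 and 7477544 for spleen CD4+ cells and 10766521 and 7559659 for spleen CD8+ cells. Between 10544 and 12103 genes had at least 1 read in a library, and the 10 most abundant genes took 10.8% to 19.2% of the reads. Values are normalised levels, given as mean ± SD.

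The sorted markers followed the labels. Cd4 had a level of 1955 ± 380 in kidney CD4+ cells and 1529 ± 233 in spleen CD4+ cells, against 17.4 ± 0.612 and 1.91 ± 2.70 in the CD8+ cells of the same organs. Cd8a had 18429 ± 180 in kidney CD8+ cells and 12173 ± 20.1 in spleen CD8+ cells, against 54.1 ± 69.1 and 1.85 ± 1.05 in CD4+ cells. In the same order, Cd8b1 had 15091 ± 2597 and 16570 ± 1389 against 52.9 ± 13 and 95.7 ± 20.6. Cd8a was at 103 in kidney CD4+ replicate 1 and 5.20 in replicate 2. The first principal component, 35.5% of the variance, placed the 4 spleen libraries between 64.2 and 73.3 and the 4 kidney libraries between -102 and -27.7.

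Kidney CD4+ replicates differed more than those of the other groups. Across genes, which are not independent replicates, log2 levels of replicates correlated at Pearson r of 0.772 in kidney CD4+, 0.883 in kidney CD8+, 0.941 in spleen CD4+ and 0.958 in spleen CD8+ cells. The SD of the log2 difference between replicates over 2543 well expressed genes was 1.58, 0.427, 0.315 and 0.336 in the same order. In kidney CD4+ replicate 2, 165 of 2604 well expressed genes lay over 2 log2 units below the lowest of the other 7 libraries, against 0 to 3 genes in any other library. Cd3e, a subunit of the T cell receptor complex, was among them at 637, against 5456 in replicate 1. Pdcd1, which encodes the inhibitory receptor PD-1, read 11103 and 580 in kidney CD4+ replicates 1 and 2, and Cxcr6, a chemokine receptor of tissue T cells, read 25829 and 1583. The deviations of kidney CD4+ replicate 2 varied with transcript length, though not in 1 direction. The median log2 deviation was 0.64 for the shortest class of transcripts, -1.05 for those of 2000 to 2500 nt and -0.25 for those over 4000 nt. Replicate 1 ran the other way, with -0.73, 0.51 and 0.28. Comparisons that involve kidney CD4+ cells rest on these 2 unlike libraries.

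**Figure D1:**
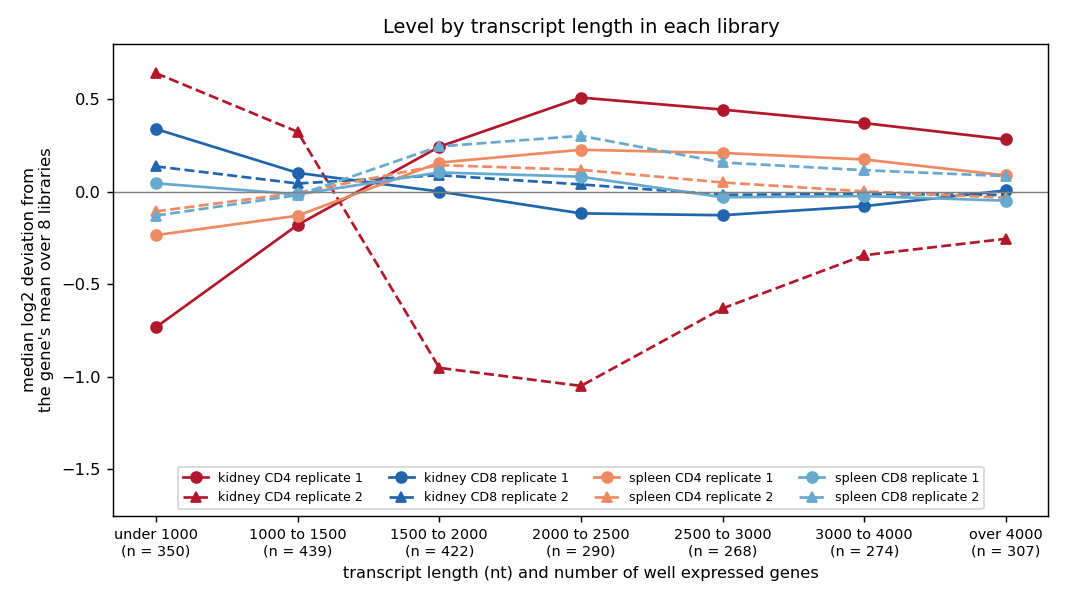
Median log2 deviation of well expressed genes from their mean over the 8 libraries (vertical axis) by class of transcript length in nt (horizontal axis), with 1 line per library and the number of genes under each class. Kidney CD4+ replicate 2 reached -1.05 at 2000 to 2500 nt, where the other 7 libraries lay between -0.12 and 0.51.

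In CD4+ T cells, the 2 largest rises and the largest fall in kidney against spleen were in genes of other cell types. Genes of kidney tubules were higher in the kidney samples. Miox, which starts the breakdown of inositol, was at least 3578-fold higher (3622 ± 3311 against 0 reads, adjusted p = 8.86e-04), and Fbp1, an enzyme of glucose synthesis, at least 2196-fold (adjusted p = 0.00174). Fxyd2, a regulatory subunit of the sodium pump (chromosome 9, 45207957 to 45218361, plus strand, mm9), was at least 5166-fold higher (5230 ± 6040 against 0 reads, adjusted p = 0.00176). Neutrophil genes were lower, with Ngp, a neutrophil granule protein, at least 2668-fold lower (0 reads against 3363 ± 1062, adjusted p = 2.25e-04) and S100a9, a subunit of calprotectin, at least 1095-fold lower (adjusted p = 3.61e-04). Among T cell genes, Crem, a transcription factor of the cyclic AMP response, was 10.3-fold higher in kidney (5024 ± 805 against 484 ± 56.4, log2 fold change 3.37 ± 0.39 SE, adjusted p = 0.00678). Il17a, the signature cytokine gene of type 17 helper cells (chromosome 1, 20720986 to 20724577, plus strand), was at 128 and 113 in the kidney replicates with 0 reads in spleen, at least 119-fold higher (adjusted p = 0.0319). In all, 87 genes were higher and 17 lower in kidney CD4+ cells. Of these, 62 and 11 had 0 reads in the other organ, and 988 genes had an unadjusted p below 0.05. The SE is pooled over the 4 groups and averages the unlike kidney CD4+ pair with closer pairs, so it can be too small here. With the 4 compared libraries alone 0 and 0 genes were called, against 131 and 48 in the CD8+ organ comparison.

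The type 17 helper list was higher in kidney CD4+ cells, with a median log2 fold change of 1.10 over 14 tested genes (camera adjusted p = 4.14e-07; adjusted p = 0.120 with an estimated correlation). Of its members 3 rose, 0 fell and 11 did not pass, with 5 rises adjusted over the list alone. Besides Il17a these were Tmem176b, a membrane protein, at 1363 ± 370 against 126 ± 42.4 (10.9-fold, adjusted p = 0.0116), and Csf2, which encodes GM-CSF. Csf2 was at 74.8 ± 0.150 against 0.831 ± 1.18 (ratio of reads 73.9, interval 24.9 to 362, adjusted p = 0.0205). The tissue residency list, genes that mark T cells staying in tissues, was higher by a median of 0.65 over 32 genes (adjusted p = 1.22e-05; adjusted p = 0.203 with an estimated correlation). It had 1 rise, Crem, and 6 rises and 1 fall adjusted over the list alone. The list of lymphoid recirculation genes was lower by a median of -0.68 over 29 genes (adjusted p = 0.00175; adjusted p = 0.203 with an estimated correlation) with 0 members called, also adjusted over the list alone. Lists of type 1 helper genes (median 0.81 over 17 genes, adjusted p = 0.00175), cytotoxic genes (0.56 over 29, adjusted p = 0.00230), TGF-beta response (0.84 over 15, adjusted p = 0.00146) and antioxidant genes (0.43 over 27, adjusted p = 0.00392) were also higher with 0 members called each. Adjusted over the list alone, 3 cytotoxic genes rose and 1 fell, 2 TGF-beta response genes rose, and 0 of the type 1 or antioxidant genes passed. With an estimated correlation these 4 lists had adjusted p = 0.165, 0.202, 0.165 and 0.313.

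The list of hypoxia and HIF-1 targets was higher in kidney CD4+ cells (median 0.15, adjusted p = 0.0493; adjusted p = 0.202 with an estimated correlation). Among 41 tested genes 4 rose, 0 fell and 37 did not pass, with 5 rises adjusted over the list alone. The 4 were Ndrg1, a stress-response gene (866 ± 662 against 34.2 ± 0.495, adjusted p = 0.0139), Mxi1, a partner of MAX (271 ± 39.1 against 30 ± 4.6, adjusted p = 0.0369), Hilpda and Ak4. Hilpda, a lipid droplet protein, was at 2301 ± 953 against 506 ± 35.7 (adjusted p = 0.0474), and Ak4 is a mitochondrial adenylate kinase (at least 115-fold higher, adjusted p = 0.0284). Ak4 and 4 other members were under 10 in every spleen library, where Miox and Fbp1 had 0 reads. RNA of tubule cells was not separated from expression in T cells for these members. Without these members, whose removal can only weaken the list, its median was 0.01 over 36 genes (camera adjusted p = 0.356). The call of the list was lost in 14 of 21 alternatives (adjusted p from 0.0172 to 0.584) and that of Hilpda in 15 of 23. Hif1a itself had a log2 fold change of 0.99 ± 0.43 (adjusted p = 0.543) and Slc2a1, a glucose transporter, 0.15 ± 0.75 (adjusted p = 0.974). Lists of glycolysis (median -0.47, adjusted p = 0.627), oxidative phosphorylation (0.16, adjusted p = 0.143), exhaustion (-0.04, adjusted p = 0.949), interferon response (-0.13, adjusted p = 0.725), cell cycle (-0.28, adjusted p = 0.225) and T cell receptor signalling (-0.01, adjusted p = 0.974) did not pass. Ifng, Gzmb, Foxp3, Tcf7, Fas and Il10 did not pass either, with log2 fold changes of 0.56, -0.60, -1.09, -0.85, -0.89 and -0.42.

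Markers of other cells moved with the organ in CD4+ cells. Of 22 tested proximal tubule markers 11 rose, 0 fell and 11 did not pass, with 17 rises adjusted over the list alone. The list was higher (median 5.87, or 6.03 with absent genes at their bound; adjusted p = 8.67e-30; adjusted p = 0.120 with an estimated correlation). Markers of the distal nephron were higher (median 3.40, or 3.90 with bounds, over 10 genes; adjusted p = 6.71e-06; adjusted p = 0.165 with an estimated correlation). They had 1 rise, Fxyd2, and 3 adjusted over the list alone. Of 12 neutrophil markers 6 fell and 6 did not pass, with 11 falls adjusted over the list alone. The list was lower (median -6.69, or -6.54 with bounds; adjusted p = 8.67e-21; adjusted p = 0.120 with an estimated correlation). Of 10 erythroid markers 3 fell, Hba-a1, Hbb-bs and Alas2, with 7 falls adjusted over the list alone. The list was lower (median -7.05, or -7.01 with bounds; adjusted p = 5.86e-08; adjusted p = 0.202 with an estimated correlation). The globin gene Hba-a1 went from 8750 ± 793 in spleen to 70.4 ± 94.6 in kidney (adjusted p = 0.0331). Macrophage markers were higher (median 1.84 over 21 genes, adjusted p = 6.71e-06; adjusted p = 0.139 with an estimated correlation). They had 1 rise, C1qb, a complement gene (2146 ± 156 against 253 ± 52.5, adjusted p = 0.0186), and 8 rises and 1 fall adjusted over the list alone. Dendritic cell markers were higher (median 1.60 over 9 genes, adjusted p = 6.75e-05; adjusted p = 0.120 with an estimated correlation). The 3 rises were the class II genes H2-Aa (7307 ± 123 against 1112 ± 91.8, adjusted p = 0.0128), H2-Eb1 and H2-Ab1, with 4 adjusted over the list alone. B cell markers were lower (median -2.36 over 9 genes, adjusted p = 0.00175; adjusted p = 0.139 with an estimated correlation) with 0 members called and 2 falls adjusted over the list alone. Markers of plasma cells (adjusted p = 0.789) and natural killer cells (adjusted p = 0.143) did not pass.

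On simulated data with the depth of these libraries the test called 0% of genes changed 2-fold, 17.9% of those changed 4-fold and 93.9% of those changed 16-fold in the CD4+ organ comparison. Of its calls 3.90% were false. Each gene had the same simulated spread in all groups, unlike the real kidney CD4+ pair, so true recovery and false calls may differ. The counts of 87 and 17 became 0 and 0 with the 4 compared libraries alone, 55 and 11 with edgeR, 273 and 79 with DESeq2 and 25 and 6 with library weights. Once the length trend was removed, 28 genes were lower. They became 804 and 1527 without kidney CD4+ replicate 1, 154 and 145 without kidney CD4+ replicate 2, 15 and 5 without spleen CD4+ replicate 1 and 12 and 3 without spleen CD4+ replicate 2. They became 39 and 9 without spleen CD8+ replicate 1 and 38 and 8 without spleen CD8+ replicate 2. Of 30 named genes called, 10 kept the call whichever library was left out, among them Acy3, Fbp1, Fxyd2, Gpx3, Keg1, Miox, Ngp, S100a8 and S100a9. Crem, Tmem176b and Ndrg1 lost it without either spleen CD4+ library (adjusted p up to 0.147, 0.177 and 0.177). It was lost for Il17a, Csf2, Mxi1, H2-Aa, H2-Ab1, H2-Eb1, Alas2 and Hbb-bs without any 1 of the 4 spleen libraries (up to 0.369) and for C1qb without any 1 of the kidney CD8+ or spleen CD4+ ones (up to 0.213). Hilpda, Ak4 and Hba-a1 lost it without any 1 library other than the kidney CD4+ ones (up to 0.466), Chil3 and Pck1 without either spleen CD4+ library (up to 0.137), and Camp and Lcn2 without spleen CD4+ replicate 2 (0.0885 and 0.0590). Among lists, residency, type 1, TGF-beta response, B cell and dendritic cell lost the call without kidney CD4+ replicate 1 (adjusted p = 0.229, 0.229, 0.108, 0.224 and 0.0743). Antioxidant lost it without replicate 2 (0.685), cytotoxic without kidney CD4+ replicate 2 or spleen CD4+ replicate 1 (up to 0.159), and hypoxia without kidney CD4+ replicate 1 or any 1 of the kidney CD8+ and spleen CD4+ libraries (up to 0.584).

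**Figure D2:**
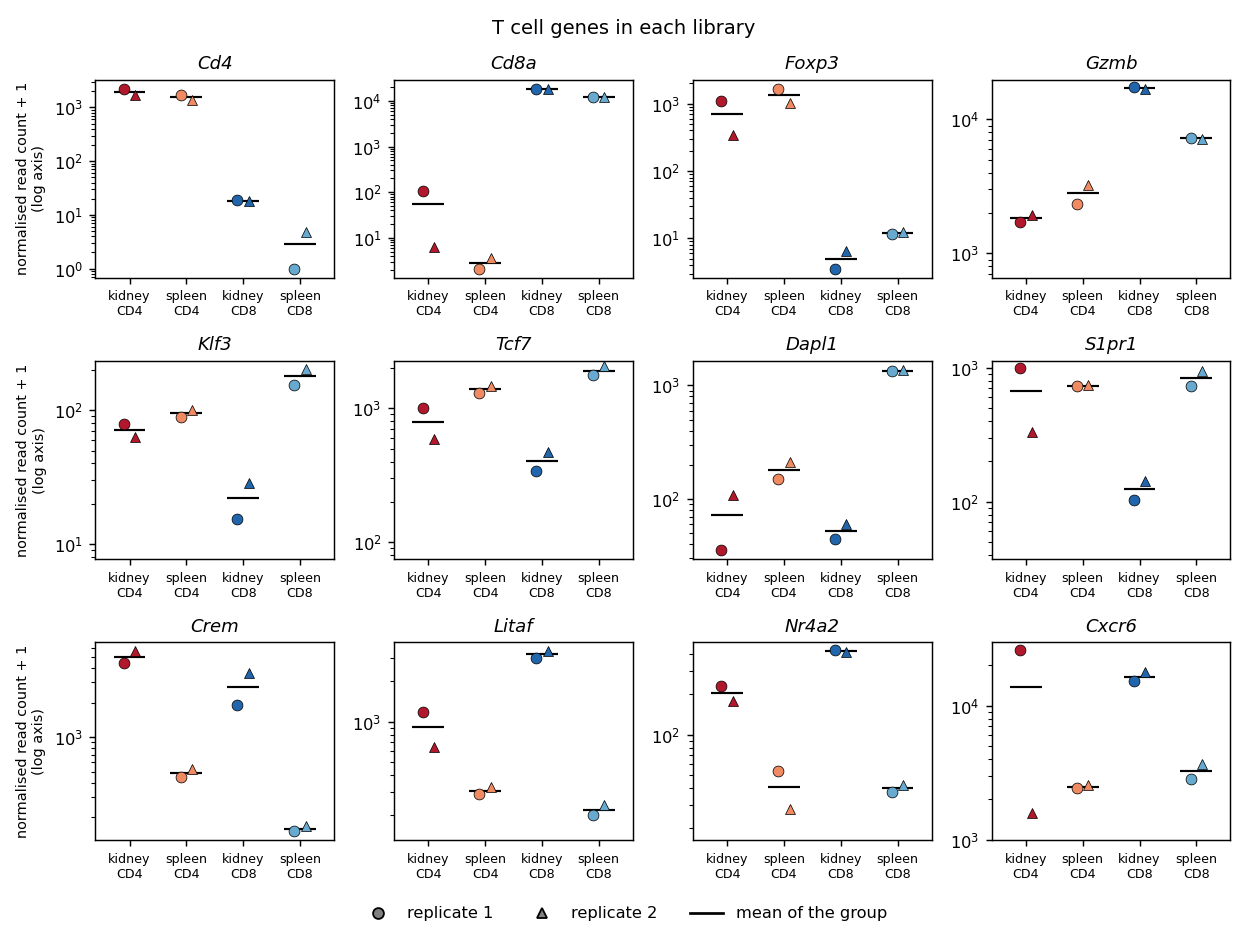
Normalised level + 1 on a log axis for 12 T cell genes in the 4 groups, with points for the 2 replicates and a line at the group mean. Crem lay higher in kidney than in spleen in both cell types, Klf3, Tcf7, Dapl1 and S1pr1 lay lower in kidney CD8+ cells, and Cxcr6 was 25829 and 1583 in the kidney CD4+ replicates.

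In CD8+ T cells, 10 of 32 tissue residency genes rose and 6 of 29 recirculation genes fell in kidney. Crem (chromosome 18, 3266046 to 3337746, minus strand, mm9) was 16.5-fold higher (2743 ± 1200 against 158 ± 11.8, log2 fold change 4.04 ± 0.39 SE, adjusted p = 0.00287). Litaf, a regulator of cytokine genes, was 14.6-fold higher (3200 ± 274 against 218 ± 27.7, adjusted p = 0.00298), and Cdh1, the adhesion protein E-cadherin, 49.3-fold higher (374 ± 67.1 against 7.30 ± 4.92, adjusted p = 0.00813). Tcf7, the transcription factor TCF1 of naive and memory T cells, was 4.75-fold lower (406 ± 97.5 against 1911 ± 208, adjusted p = 0.0284). S1pr1, the receptor that guides exit from tissues, was 6.84-fold lower (122 ± 28.8 against 837 ± 149, adjusted p = 0.0412). In all, 131 genes were higher and 37 lower in kidney CD8+ cells, 72 and 13 of them with 0 reads in the other organ, out of 1147 at an unadjusted p below 0.05.

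Of 32 residency genes 10 rose, 0 fell and 22 did not pass, with 17 rises adjusted over the list alone. The list was higher (median 2.17, camera adjusted p = 2.85e-17; adjusted p = 0.0640 with an estimated correlation). Nr4a2, a transcription factor induced by receptor signals, was a member at 418 ± 9.56 against 38.7 ± 3.32 (adjusted p = 0.0136). Itgae, the integrin CD103, had a log2 fold change of 2.73 ± 0.85 (adjusted p = 0.234) and Cxcr6 2.35 ± 1.04 (adjusted p = 0.479). Both SEs are pooled over the 4 groups, so they include the kidney CD4+ pair, whose Cxcr6 levels were far apart. Of 29 recirculation genes 6 fell, 0 rose and 23 did not pass, with 15 falls adjusted over the list alone. The list was lower (median -1.94, adjusted p = 1.41e-16; adjusted p = 0.0640 with an estimated correlation). Among the falls were Dapl1 (51.3 ± 11.4 against 1346 ± 22.0, adjusted p = 0.00743) and Klf3, a repressor of lymphocyte trafficking genes (8.40-fold lower, adjusted p = 0.0284). The TGF-beta response list was higher with 3 rises among 15 genes and 8 adjusted over the list alone (median 1.28, adjusted p = 2.83e-07; adjusted p = 0.0640 with an estimated correlation). The 3 were Cdh1, Ldlrad4 (4.35-fold, adjusted p = 0.0277) and Nrp1 (4.81-fold, adjusted p = 0.0494). The type 17 list was higher with 4 rises among 14 genes and 8 adjusted over the list alone (median 2.38, or 2.56 with bounds; adjusted p = 1.41e-08; adjusted p = 0.0640 with an estimated correlation). The 4 were Tmem176a (18.6-fold, adjusted p = 0.0133), Tmem176b (10.9-fold, adjusted p = 0.00989), S100a4 (5.50-fold, adjusted p = 0.025) and Csf2 (19.3-fold, adjusted p = 0.0459).

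The exhaustion list, genes of T cells under lasting stimulation, was higher in kidney CD8+ cells (median 1.04 over 25 genes, adjusted p = 1.79e-06; adjusted p = 0.221 with an estimated correlation). Its 2 rises were Nr4a2 and Nr4a3 (43.3-fold, adjusted p = 0.0130), which are also immediate early genes, with 3 rises adjusted over the list alone. Pdcd1 was at 4795 ± 322 against 958 ± 74.6 (log2 fold change 2.32 ± 1.08 SE, adjusted p = 0.507). The SE is pooled over all 4 groups, so it includes the unlike kidney CD4+ pair, which is not part of this comparison. It was 0.13 with the compared libraries alone (adjusted p = 0.0182), and 0.16 and 0.15 without kidney CD4+ replicates 1 and 2 (adjusted p = 1.80e-04 and 1.97e-04, in a range of 1.80e-04 to 1 over 23 alternatives). Immediate early and dissociation stress genes were higher as a list with the same 2 rises among 34 genes and 4 adjusted over the list alone (median 0.48, adjusted p = 0.0363; adjusted p = 0.221 with an estimated correlation). Cytotoxic genes were higher (median 0.96 over 29 genes, adjusted p = 2.76e-05; adjusted p = 0.131 with an estimated correlation). They had 1 rise, the chemokine gene Ccl3 (15399 ± 5334 against 2501 ± 637, adjusted p = 0.0453), and 7 rises and 1 fall adjusted over the list alone. Type 1 helper genes were higher (median 0.96 over 17, adjusted p = 0.00402; adjusted p = 0.164 with an estimated correlation) with Ccl3 as the 1 rise and 5 adjusted over the list alone. Ifng, the gene of interferon gamma, was at 11627 ± 2360 against 3772 ± 354 (adjusted p = 0.0752) and Gzmb, a granzyme gene, at 17258 ± 482 against 7232 ± 58.9 (adjusted p = 0.162). Like Pdcd1, both passed when either kidney CD4+ library was left out (adjusted p up to 0.00205 for Ifng and 0.00477 for Gzmb, in ranges of 0.00150 to 0.624 and 0.00406 to 0.839). Some genes of lists that did not pass were called. Capg (3.95-fold, adjusted p = 0.0212), Nrp1 and Tnfrsf4, which encodes OX40 (3.88-fold, adjusted p = 0.0307), are regulatory T cell genes. Icos, a costimulatory receptor gene (4.71-fold, adjusted p = 0.0395), and Tnfsf8 (6.09-fold lower, adjusted p = 0.0241) are follicular helper genes. The regulatory T cell list had adjusted p = 0.130 and the follicular helper list 0.496.

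Hypoxia and HIF-1 targets were higher as a list in kidney CD8+ cells (median 0.30, adjusted p = 0.0155; adjusted p = 0.150 with an estimated correlation). Of 41 genes 4 rose, with 5 rises adjusted over the list alone. The 4 were Ndrg1 (25.3-fold, adjusted p = 0.00890), Hilpda (4.54-fold, adjusted p = 0.0320), Selenbp1 (327 ± 261 against 1.68 ± 2.38, adjusted p = 0.00918) and Ak4 (at least 66.1-fold, adjusted p = 0.0254). Selenbp1 and Ak4 were among the 5 members under 10 in every spleen library. Ak4 had 0 reads in spleen, as did the tubule genes Miox and Fbp1. For such members RNA of tubule cells was not separated from expression in T cells. Without these 5 members the list had a median of 0.23 over 36 genes (camera adjusted p = 0.118). Their removal can only weaken the list and is in no count of alternatives. The call of the list was lost in 2 of 21 alternatives (adjusted p from 4.97e-04 to 0.150). Genes of oxidative phosphorylation were higher (median 0.37 over 76 genes, adjusted p = 0.0198; adjusted p = 0.670 with an estimated correlation). Ribosomal protein genes were lower (median -0.30 over 52, adjusted p = 0.00518; adjusted p = 0.670 with an estimated correlation). Neither list had a member called (0 and 0), also adjusted over the list alone. Glycolysis (adjusted p = 0.641), interferon response (0.253), cell cycle (0.641), T cell receptor signalling (0.198) and apoptosis (0.118) lists did not pass. Neither did Hif1a (log2 fold change 0.56 ± 0.43, adjusted p = 0.733) or Fas (-0.08 ± 0.47, adjusted p = 0.976).

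Markers of other cells moved with the organ in CD8+ cells as well. Proximal tubule markers were higher with 12 rises among 22 genes and 17 adjusted over the list alone (median 5.41, or 5.49 with bounds; adjusted p = 4.75e-27; adjusted p = 0.0640 with an estimated correlation). Pck1, an enzyme of glucose synthesis, was at least 999-fold higher. Distal nephron markers were higher (median 2.57, or 2.74 with bounds; adjusted p = 0.00138; adjusted p = 0.221 with an estimated correlation). They had 1 rise, Fxyd2, at least 2646-fold, and 2 adjusted over the list alone. Neutrophil markers were lower with 7 falls among 12 genes and 10 adjusted over the list alone (median -7.02, or -6.89 with bounds; adjusted p = 6.71e-21; adjusted p = 0.0640 with an estimated correlation), and Ngp was at least 1841-fold lower. Erythroid markers were lower with 7 falls among 10 genes, also adjusted over the list alone (median -7.86, adjusted p = 6.62e-09; adjusted p = 0.185 with an estimated correlation). The 1 rise was Car2, a carbonic anhydrase gene that many cells express (log2 fold change 2.96 ± 0.49, adjusted p = 0.0270; chosen after its values were seen). B cell markers had 1 fall among 9 genes, Cd79b (3.66-fold, adjusted p = 0.0353), and 6 adjusted over the list alone. The list was lower (median -3.28, adjusted p = 1.46e-07; adjusted p = 0.0640 with an estimated correlation). Macrophage markers had 2 rises among 21 genes, C1qa (11-fold, adjusted p = 0.0335) and C1qb (7.79-fold, adjusted p = 0.0189), and 5 rises and 1 fall adjusted over the list alone. The list was higher (median 1.30, adjusted p = 0.00434; adjusted p = 0.221 with an estimated correlation). Dendritic cell (adjusted p = 0.0537), natural killer cell (0.118) and plasma cell (0.409) markers did not pass.

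Simulated data gave 1.49%, 19.4% and 92.4% of changed genes called for 2-fold, 4-fold and 16-fold changes in the CD8+ organ comparison, with 6.17% of calls false. The counts of 131 and 37 became 363 and 129 with DESeq2 and 402 and 175 with library weights. With edgeR 74 genes were higher, and 66 genes were lower once the length trend was removed. They became 483 and 254 without kidney CD4+ replicate 1, 466 and 258 without kidney CD4+ replicate 2, 30 and 7 without kidney CD8+ replicate 1, 25 and 36 without kidney CD8+ replicate 2. They became 64 and 14 without spleen CD4+ replicate 1, 56 and 12 without spleen CD4+ replicate 2, 16 and 5 without spleen CD8+ replicate 1 and 23 and 4 without spleen CD8+ replicate 2. Of 47 named genes called, 11 kept the call whichever library was left out, among them Akr1c21, Fbp1, Fxyd2, Gpx3, Keg1, Lcn2, Miox, Ngp, S100a8 and S100a9. Crem and Litaf lost it only without spleen CD8+ replicate 1 (adjusted p = 0.0602 and 0.0670), and Cdh1, Dapl1, Ndrg1, Tmem176b and Nr4a2 without any 1 of the 4 CD8+ libraries (up to 0.182). Tcf7, S1pr1, Klf3, Csf2, Ccl3, Icos, Hilpda, Ak4, S100a4, Ldlrad4, Nrp1, Capg, Tnfrsf4, Tnfsf8, Cd79b, C1qa and C1qb lost it without any 1 library other than the kidney CD4+ ones (up to 0.447), and Nr4a3, Tmem176a, Selenbp1 and Pck1 without some of the CD8+ libraries (up to 0.145). The lists that lost the call were hypoxia without kidney CD8+ replicate 2 (adjusted p = 0.0886), oxidative phosphorylation without kidney CD8+ replicate 1 or spleen CD8+ replicate 2 (up to 0.30). Ribosomal protein lost it without kidney CD8+ replicate 2 or spleen CD8+ replicate 1 (up to 0.303), and immediate early without any 1 of the 4 kidney libraries or spleen CD8+ replicate 1 (up to 0.0985).

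**Figure D3:**
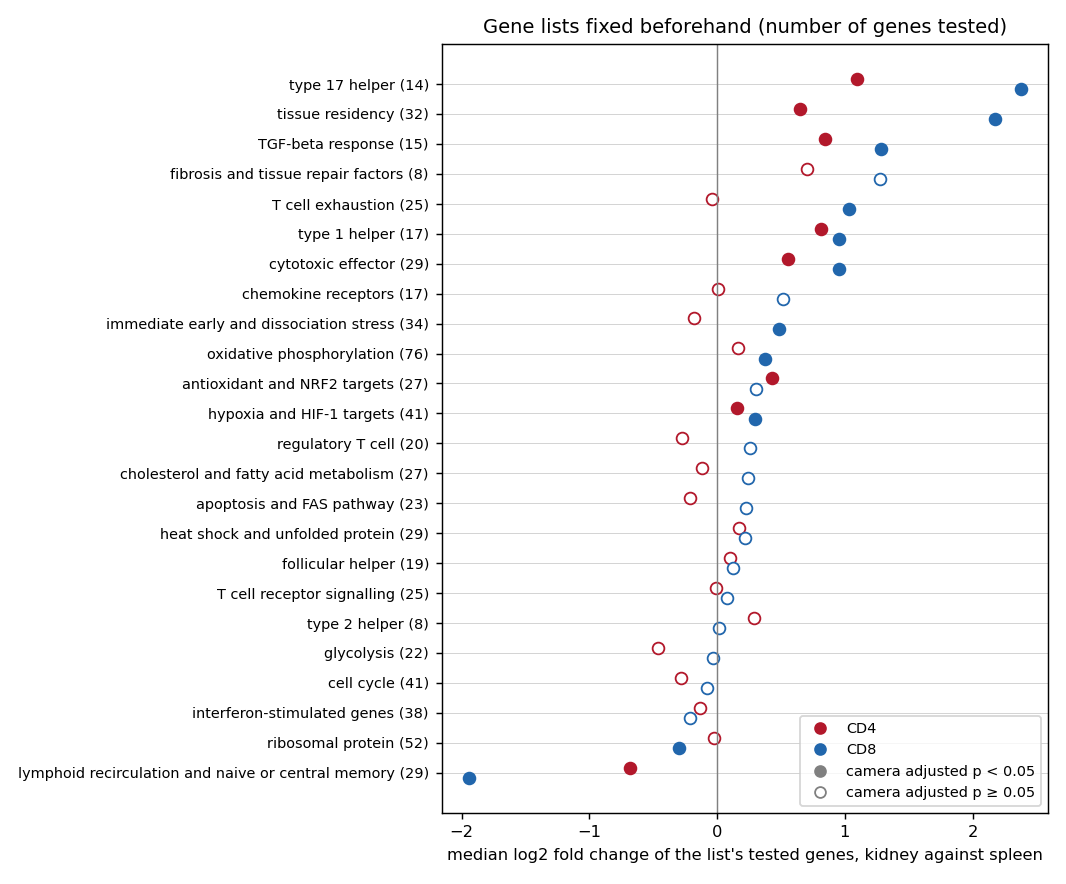
Median log2 fold change of kidney against spleen (horizontal axis) for 24 gene lists other than cell markers (vertical axis), in CD4+ cells (red) and CD8+ cells (blue), with filled symbols where the camera adjusted p was below 0.05. Residency reached 2.17 in CD8+ cells and 0.65 in CD4+ cells, and recirculation -1.94 and -0.68.

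Many organ differences were shared by the samples of the 2 cell types. Of the genes higher in kidney, 70 were called in both, where independent lists would share 1.05, and of those lower, 14 were, where independent lists would share 0.0580. The 2 comparisons share no libraries but use 1 variance estimate per gene. Their calls are therefore not independent, and these baselines are no test. Of the 70, 51 had 0 reads in all 4 spleen libraries and 7 reached 10 in some spleen library. The tubule genes Miox, Fbp1 and Fxyd2 were among the 70. Of the 14, 8 had 0 reads in all 4 kidney libraries and 3 reached 10 in some kidney library. Samples of the same organ can share RNA of other cells, so these counts do not show a change common to the T cells. All 87 CD4+ calls higher in kidney had the same sign in CD8+ cells, as did all 17 lower, and 128 of 131 and 36 of 37 CD8+ calls had the same sign in CD4+ cells. The counts of 70 and 14 became 0 and 0 with the compared libraries alone, 42 and 9 with edgeR, 201 and 30 with DESeq2 and 24 and 6 with library weights. They became 284 and 153 without kidney CD4+ replicate 1, 107 and 33 without kidney CD4+ replicate 2, 28 and 6 without kidney CD8+ replicate 1, 23 and 10 without kidney CD8+ replicate 2. They became 15 and 5 without spleen CD4+ replicate 1, 12 and 3 without spleen CD4+ replicate 2, 13 and 5 without spleen CD8+ replicate 1 and 18 and 4 without spleen CD8+ replicate 2.

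As shares of all reads, proximal tubule markers took 0.141% and 0.237% in the kidney CD4+ libraries and 0.0817% and 0.292% in the kidney CD8+ libraries, against 0.00177% to 0.0115% in spleen. Neutrophil markers took 0.0509% to 0.147% in spleen and up to 0.00268% in kidney, and erythroid markers 0.190% to 0.419% in spleen and 0.00966% to 0.0254% in kidney. Dendritic cell markers took 0.424% and 0.192% in kidney CD4+ cells, against 0.0356% to 0.0927% in the other 6 libraries, and macrophage markers 0.244% and 0.153%, against 0.0486% to 0.120%.

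**Figure D4:**
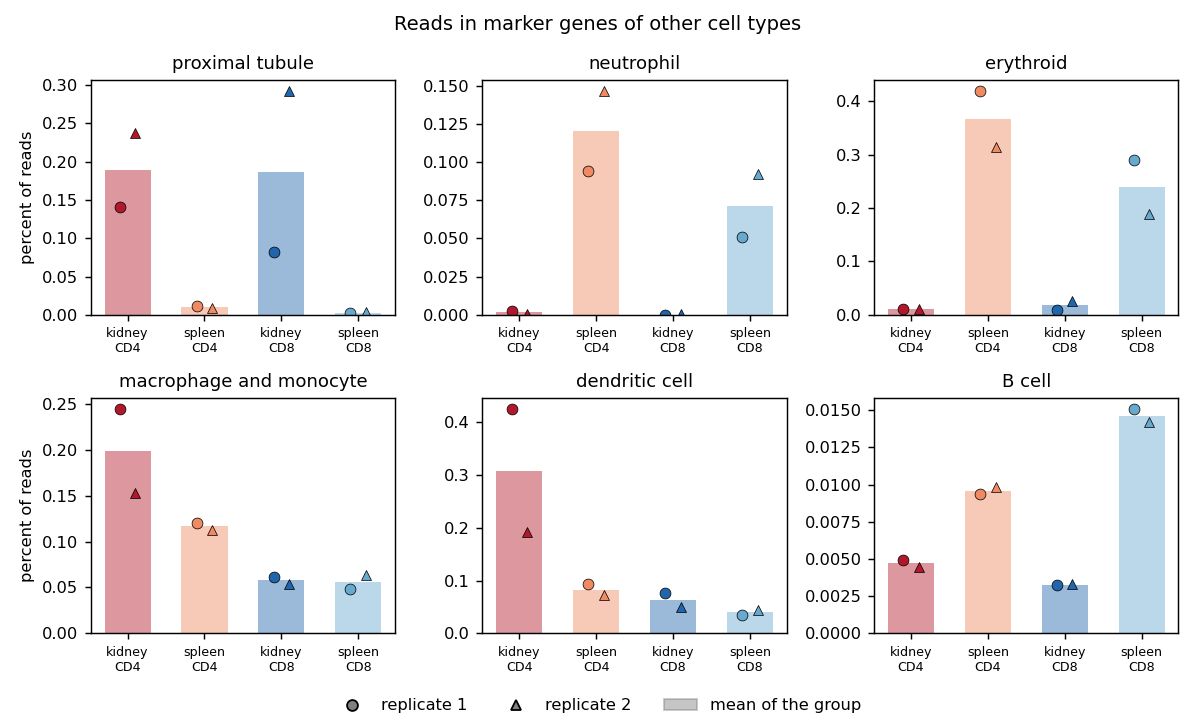
Percent of all reads (vertical axes, from 0) in markers of 6 other cell types, with bars at the group mean and points for the 2 libraries of each group. Tubule markers lay between 0.0817% and 0.292% in kidney and at most 0.0115% in spleen, and erythroid markers at most 0.0254% in kidney and at least 0.190% in spleen.

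No gene had an organ difference that differed between CD8+ and CD4+ cells by limma (0 calls), edgeR called 0 and DESeq2 12. Of the 10845 genes tested, 362 had an unadjusted limma p below 0.05, a smaller share than the 0.05 that no difference at all would give. Gene lists did differ, with camera but not with an estimated correlation. The organ difference of the residency list was higher in CD8+ cells by a median log2 of 0.97 (adjusted p = 3.40e-08; adjusted p = 0.378 with an estimated correlation). It had 0 members called and 4 rises adjusted over the list alone, Qpct, Cish, Litaf and Cd244. For Litaf the difference was 2.35 ± 0.54 SE (unadjusted p = 0.00219, adjusted p = 0.999), and for Qpct, an enzyme that modifies protein ends, 4.34 ± 0.94 (adjusted p = 0.999). That of the recirculation list was lower by -1.20 (adjusted p = 1.84e-09; adjusted p = 0.375 with an estimated correlation). That of the exhaustion list was higher by 1.17 (adjusted p = 8.24e-07; adjusted p = 0.435 with an estimated correlation). Both had 0 members called, also adjusted over the list alone. Kidney CD4+ replicate 2 bears on these differences, since Pdcd1 read 11103 and 580 in the kidney CD4+ replicates and the difference of organ effects for Pdcd1 was 2.22 ± 1.53 (adjusted p = 0.999). Without kidney CD4+ replicate 1, 745 genes were called, and without replicate 2, 8 genes. The 3 lists kept their calls whichever library was left out, but without kidney CD4+ replicate 2 the median of the exhaustion list went from 1.17 to 0.36. Between CD8+ and CD4+ cells of the spleen the 3 lists passed at the preset correlation but not with an estimated correlation, as given below. Within the kidney none did in the main fit, with medians of 0.07 for residency, -0.56 for recirculation and 0.17 for exhaustion (adjusted p = 0.235, 0.0867 and 0.956). Of 21 alternatives, recirculation passed as lower in CD8+ cells in 3 (adjusted p from 0.0191 to 0.568), residency as higher in 1 (0.0371 to 0.804) and exhaustion as lower in 1 (0.0478 to 0.999).

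Between CD8+ and CD4+ cells within the kidney, cytotoxic genes were higher and follicular helper, type 2 helper and regulatory T cell genes lower in CD8+ cells, as lists. The type 1 helper list did not pass (median 0.45, adjusted p = 0.110). Gzma, a granzyme gene, was 26.2-fold higher (7318 ± 305 against 314 ± 204, log2 fold change 4.71 ± 0.48 SE, adjusted p = 0.0101). Gzmb was 9.48-fold higher (17258 ± 482 against 1822 ± 166, adjusted p = 0.0107), and Klrc1, a lectin-like receptor gene, 15.1-fold higher (5869 ± 48.5 against 405 ± 171, adjusted p = 0.00754). Foxp3, the transcription factor of regulatory T cells, was 128-fold lower (3.97 ± 2.02 against 710 ± 523, adjusted p = 0.00715) and Tnfrsf4 71.0-fold lower (282 ± 54.6 against 20041 ± 3009, adjusted p = 2.43e-04). Of 29 cytotoxic genes 4 rose, 0 fell and 25 did not pass, with 17 rises and 1 fall adjusted over the list alone (median 1.48, adjusted p = 1.71e-18). Of 20 regulatory T cell genes 5 fell and 15 did not pass, with 16 falls and 1 rise adjusted over the list alone (median -3.71, adjusted p = 1.71e-18). Follicular helper genes were lower with 2 falls among 19 genes, Tnfsf8 and Angptl2, and 9 adjusted over the list alone (median -2.57, or -3.08 with bounds; adjusted p = 2.14e-12). These 3 lists kept the call with an estimated correlation (adjusted p = 0.0338 each). Type 2 helper genes were lower with 0 members called and 8 falls among 8 genes adjusted over the list alone (median -4.26, or -4.10 with bounds; adjusted p = 3.98e-11; adjusted p = 0.0570 with an estimated correlation).

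Further lists passed in this comparison within the kidney. Macrophage markers were lower in CD8+ cells (median -2.16 over 21 genes, adjusted p = 1.51e-10; adjusted p = 0.0570 with an estimated correlation) with 0 members called and 7 falls adjusted over the list alone. Type 17 genes (median -0.75, adjusted p = 0.00346), chemokine receptors (-0.55, adjusted p = 0.0104), dendritic cell markers (-0.55, adjusted p = 0.0268) and B cell markers (-1.73, adjusted p = 0.0387) were lower, and oxidative phosphorylation (0.38, adjusted p = 0.00532), ribosomal protein (0.41, adjusted p = 3.08e-04) and natural killer cell genes (0.22, adjusted p = 0.0419) higher. With an estimated correlation these 7 lists had adjusted p = 0.236, 0.744, 0.236, 0.236, 0.804, 0.804 and 0.236. Gzma, in the natural killer cell list, was their only member called. Adjusted over the list alone, 2 type 17, 3 chemokine receptor and 3 dendritic cell genes fell, 4 natural killer cell genes rose and 0 members of the other 3 lists passed. In all, 13 genes were higher and 9 lower in kidney CD8+ cells, out of 923 at an unadjusted p below 0.05. Simulated data gave 1.49%, 25.4% and 89.4% of changed genes called for 2-fold, 4-fold and 16-fold changes, with 3.70% of calls false. The simulated spread was the same in all groups, unlike that of the real kidney CD4+ pair, so true values may differ. As in the CD4+ organ comparison, the SE pooled over the 4 groups can be too small here, because the kidney CD4+ pair spread most. The 22 genes became 0 with the compared libraries alone, 216 with DESeq2, 12 with library weights, 38 with a pseudocount of 5, 39 with quantile scaling and 43 once the length trend was removed. They became 1180 without kidney CD4+ replicate 1, 1351 without kidney CD4+ replicate 2, 3 and 10 without kidney CD8+ replicates 1 and 2, 4 without either spleen CD4+ library, and 6 and 8 without spleen CD8+ replicates 1 and 2. Of the 18 named genes called, Cd8b1, Tnfrsf4 and Izumo1r kept the call whichever library was left out, and Gzma, Gzmb, Klrk1, Cd160, Qpct, Cd8a, Cd9, Cd244, Klra5, Nrp1 and Angptl2 lost it without any 1 library other than the kidney CD4+ ones (adjusted p up to 0.286). Klrc1, Cd4, Foxp3 and Tnfsf8 lost it without some of these (up to 0.255, 0.255, 0.201 and 0.103). The oxidative phosphorylation, ribosomal protein and chemokine receptor lists changed direction without kidney CD4+ replicate 1 (adjusted p = 1.46e-04, 1.15e-05 and 0.748). Type 17 lost the call without kidney CD4+ replicate 2 (0.423), B cell without kidney CD4+ replicate 2 or either kidney CD8+ library (up to 0.552) and dendritic cell without kidney CD4+ replicate 1 or kidney CD8+ replicate 2 (up to 0.152). Natural killer cell lost it without either kidney CD4+ library, kidney CD8+ replicate 1 or either spleen CD4+ library (up to 0.260). Oxidative phosphorylation also lost it without kidney CD8+ replicate 1 (0.156), and chemokine receptors without kidney CD8+ replicate 2.

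In the spleen, the same comparison gave 14 genes higher and 25 lower in CD8+ cells, out of 697 at an unadjusted p below 0.05. Gzma was 28.4-fold higher (7680 ± 331 against 274 ± 73.4, adjusted p = 0.00645), Klrk1, which encodes NKG2D, 12.9-fold higher (1410 ± 104 against 109 ± 17.2, adjusted p = 0.00321). Ly6c2, a surface antigen of memory CD8+ cells, was 31.1-fold higher (47620 ± 367 against 1638 ± 833, adjusted p = 0.0183). Foxp3 was 107-fold lower (11.1 ± 0.484 against 1337 ± 464, adjusted p = 0.00598), Tnfrsf4 136-fold lower (adjusted p = 7.44e-05), Maf, a transcription factor of helper cells, 16.9-fold lower (adjusted p = 0.00737). Cd40lg, the helper signal to B cells, had a ratio of reads of 1437 (interval 258 to 56802) in favour of CD4+ cells (adjusted p = 0.0187). Of 29 cytotoxic genes 5 rose and 24 did not pass, with 10 rises adjusted over the list alone (median 0.94, adjusted p = 1.03e-18). Of 20 regulatory T cell genes 8 fell and 12 did not pass, with 15 falls adjusted over the list alone (median -4.01, or -3.98 with bounds; adjusted p = 1.13e-32). Follicular helper genes were lower with 3 falls among 19 genes and 8 adjusted over the list alone (median -1.57, adjusted p = 1.16e-12). Type 2 helper genes were lower with 1 fall, Maf, among 8 and 7 adjusted over the list alone (median -3.99, or -3.96 with bounds; adjusted p = 1.84e-13). These 4 lists kept the call with an estimated correlation (adjusted p = 0.0324, 0.0324, 0.0324 and 0.0418).

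Spleen CD8+ cells also had lower exhaustion genes (median -1.0 over 25, adjusted p = 2.60e-06; adjusted p = 0.315 with an estimated correlation). They had 2 falls, Ikzf2 (10.2-fold) and Cd200r1 (21.6-fold), and 2 rises and 7 falls adjusted over the list alone. Residency genes were lower (median -0.76 over 32, adjusted p = 2.37e-05; adjusted p = 0.315 with an estimated correlation) with 1 fall, Icos, and 1 rise and 7 falls adjusted over the list alone. Icos was named above as a follicular helper gene, and the follicular helper and regulatory T cell lists were also lower here. Neither the exhaustion nor the residency list was tested without genes of CD4+ helper or regulatory cells, so differences of lineage were not separated. Recirculation genes were higher (median 0.54 over 29, adjusted p = 6.54e-08; adjusted p = 0.102 with an estimated correlation) with 1 member called in the other direction and 4 rises and 1 fall adjusted over the list alone. The member called was Ly6c1 (log2 fold change -3.38, adjusted p = 0.0193), a surface antigen gene close in sequence to Ly6c2. Ribosomal protein genes were higher (median 0.67 over 52, adjusted p = 1.84e-13; adjusted p = 0.492 with an estimated correlation). Oxidative phosphorylation (0.14, adjusted p = 0.0220; adjusted p = 0.853 with an estimated correlation) and natural killer cell genes (0.99, adjusted p = 0.0166; adjusted p = 0.178 with an estimated correlation) were also higher. Glycolysis (median -0.41, adjusted p = 0.0225; adjusted p = 0.622 with an estimated correlation), type 17 genes (-1.39, adjusted p = 1.09e-04; adjusted p = 0.154 with an estimated correlation) and macrophage markers (-1.74, adjusted p = 1.51e-08; adjusted p = 0.0856 with an estimated correlation) were lower. Of these 6 lists the only member called was Gzma, in the natural killer cell list. Adjusted over the list alone, 5 natural killer cell genes rose and 2 fell, 1 type 17 gene rose and 5 fell, 5 macrophage markers fell, and 0 members of the other 3 lists passed. Simulated data gave 1.49%, 16.4% and 92.4% of changed genes called for 2-fold, 4-fold and 16-fold changes in the spleen comparison, with 2.67% of calls false. The 39 genes became 142 with the compared libraries alone, 234 with DESeq2, 666 with library weights and 74 with a pseudocount of 5. They became 60 with TMM scaling, 62 with quantile scaling and 74 once the length trend was removed. They became 323 and 316 without kidney CD4+ replicates 1 and 2, 12 and 17 without kidney CD8+ replicates 1 and 2, 2 without either spleen CD4+ library, and 4 and 3 without spleen CD8+ replicates 1 and 2. Cd8b1 and Tnfrsf4 kept the call whichever library was left out, and the other 23 named genes called lost it without at least 1 of the spleen or kidney CD8+ libraries (adjusted p up to 0.571). So did the glycolysis and oxidative phosphorylation lists without spleen CD4+ replicate 1 or spleen CD8+ replicate 1 (up to 0.126 and 0.249).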

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

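The tests without kidney CD4+ replicate 2 and after removal of the length trend were written before their results were seen, and removal of the length trend was added after the data were seen. The tests of the 3 lists within the kidney under alternatives were chosen after the result was seen. For 7 gene lists the difference between kidney and spleen was itself different in CD8+ and CD4+ cells, by a camera test of the interaction. Limma and edgeR called 0 single genes and DESeq2 12. Of 10845 genes, 362 had an unadjusted limma p below 0.05, a smaller share than 0.05. Lymphoid recirculation genes had a median difference of -1.20 (adjusted p = 1.84e-09), tissue residency genes 0.97 (3.40e-08), exhaustion genes 1.17 (8.24e-07) and dendritic cell markers -0.83 (0.0107). Regulatory T cell genes had 0.72 (0.0166), TGF-beta response genes 0.79 (0.0238) and B cell markers -1.73 (0.0277). With an estimated correlation none of the 7 was called (adjusted p = 0.375, 0.378, 0.435, 0.378, 0.435, 0.435 and 0.378), and fry called 0 of them. With 1 library left out, TGF-beta response lost the call without any 1 of the 4 kidney libraries, spleen CD4+ replicate 1 or spleen CD8+ replicate 2 (adjusted p up to 0.159), and B cell without the same libraries except kidney CD4+ replicate 1 (up to 0.342). Regulatory T cell lost it without kidney CD4+, kidney CD8+ or spleen CD8+ replicate 2 or spleen CD4+ replicate 1 (up to 0.219), and dendritic cell without kidney CD4+ replicate 1, kidney CD8+ replicate 2 or spleen CD4+ replicate 1 (up to 0.204). Recirculation, residency and exhaustion kept it whichever library was left out. Over their 20 alternatives the adjusted p ranged from 7.24e-13 to 0.375, 4.10e-10 to 0.402 and 4.23e-09 to 0.435.

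The larger organ difference of the residency, recirculation and exhaustion lists in CD8+ cells was weighed against the unlike library, kidney CD4+ replicate 2. Without that library the residency list kept an adjusted p of 0.00581 with 83.1% of its median, and the recirculation list 1.63e-06 with 130% of its median, which argues against that library alone as the cause for these 2 lists. The exhaustion list kept an adjusted p of 0.0148 but only 30.9% of its median (0.36 against 1.17), so for exhaustion that library and a cell type difference cannot be told apart. Without kidney CD4+ replicate 1 instead, the medians of residency, recirculation and exhaustion were 1.54, -1.31 and 1.87, so their size depended on the library kept. After removal of each library's trend on transcript length, the 3 lists had adjusted p = 7.90e-10, 2.65e-10 and 1.49e-07 in the order residency, recirculation and exhaustion. They kept at least 85.2% of their medians, which argues against the trend that was removed, as the whole cause. Removal still left 60 well expressed genes far below the other libraries in kidney CD4+ replicate 2, against 5 in the next library. Deviations of that library that the removal missed are therefore not covered. Set side by side within each organ, CD8+ and CD4+ cells differed in the spleen for all 3 lists at the preset correlation, in the same order with medians of -0.76, 0.54 and -1.0 (adjusted p = 2.37e-05, 6.54e-08 and 2.60e-06). With an estimated correlation none of the 3 passed in the spleen. In the kidney none passed in the main fit, with 0.07, -0.56 and 0.17 (adjusted p = 0.235, 0.0867 and 0.956). Without kidney CD4+ replicate 2 the kidney medians were -0.36, -1.17 and -0.55 (adjusted p = 0.566, 0.154 and 0.0478), and without replicate 1 they were 0.51, -0.19 and 0.59 (adjusted p = 0.0371, 0.283 and 0.0898). The kidney medians of residency and exhaustion thus changed sign with the library kept. After removal of the length trend, recirculation passed as lower in kidney CD8+ cells (median -0.62, adjusted p = 0.0191), as it did in 3 of 21 alternatives (0.0191 to 0.568), and it was lower in all 21. Whether kidney CD8+ cells are more resident than kidney CD4+ cells stays open. A difference between the cell types in the spleen and one in the kidney both stay open as sources of the larger organ difference, and the calls rest on the preset correlation.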

How the results depend on the processing

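Library weights, removal of the length trend and the hypoxia list without 5 members near 0 in spleen were tests chosen after the data were seen, and the others were planned. Calls under alternatives kept their direction except for 3 lists between cell types in kidney, which reversed without kidney CD4+ replicate 1, chemokine receptors (adjusted p = 0.748), oxidative phosphorylation (1.46e-04) and ribosomal protein (1.15e-05). With each library left out in turn these 3 ranged from 6.42e-06 to 0.748, 1.43e-18 to 0.156 and 1.22e-30 to 0.0401. Over all alternatives, named genes kept the call in 555 of 690 cases for CD4+ cells between organs, 850 of 1081 for CD8+ cells, 307 of 414 between cell types in kidney and 439 of 575 in spleen. Lists kept it in 273 of 313, 321 of 355, 212 of 250 and 249 of 272 cases in the same order, and in 104 of 139 for the difference between cell types. The shortened hypoxia list can only lose rises and is in none of these counts. Where a count moved the cause was not tested, except that fewer libraries were fitted in the settings that leave some out.

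The 4 compared libraries alone gave 0 and 0 genes higher and lower in kidney CD4+ cells, 0 shared by both cell types in either direction, 0 between cell types in kidney and 142 in spleen. With edgeR these were 55 and 11 for CD4+, 74 higher for CD8+, and 42 and 9 shared, and 54 of the 55 were among the 87. With DESeq2 they were 273 and 79, 363 and 129, 201 and 30 shared, 12 for the difference between cell types, 216 in kidney and 234 in spleen. Library weights gave 25 and 6, 402 and 175, 24 and 6 shared, 12 in kidney and 666 in spleen, with a weight of 0.239 for kidney CD4+ libraries and 0.888 to 2.45 for the others. Removal of the length trend gave 28 lower for CD4+, 66 lower for CD8+, 43 in kidney and 74 in spleen. A pseudocount of 5 gave 38 and 74 in kidney and spleen, quantile scaling 39 and 62, and TMM scaling 60 in spleen. The median log2 fold change over all genes moved for CD4+ cells by 0.11 with edgeR, 0.16 with DESeq2 and 0.21 without kidney CD4+ replicate 2. Between cell types in kidney 13 genes were higher and 9 lower (59.1% higher), against 16 and 23 with quantile scaling (41.0%), 88 and 128 with DESeq2 (40.7%) and 19 and 24 after removal of the length trend (44.2%). With 1 library left out the share was 10% to 83.6%.

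With an estimated correlation 0, 0, 0, 3 and 4 lists were called for CD4+, CD8+, their difference, kidney and spleen, against 15, 17, 7, 12 and 13, and fry called 10, 15, 0, 7 and 7. With 1 library left out, which assumes that a lone library varies like the other groups, genes ranged from 12 to 804 higher and 3 to 1527 lower for CD4+, and 16 to 483 and 4 to 258 for CD8+. They ranged from 0 to 745 for the difference, 3 to 1351 in kidney, 2 to 323 in spleen, and 12 to 284 and 3 to 153 shared. Lists ranged over 13 to 20, 14 to 18, 3 to 10, 10 to 16 and 12 to 14. The replicate number as a block gave 74 and 16 for CD4+, 109 and 28 for CD8+, 18 in kidney, 19 in spleen and 0 for the difference. Deviations of same-numbered libraries correlated between -0.155 and 0.0559, so the numbers were not taken as pairs. With 2 libraries per group at the depth of this data, at most 1.49% of 2-fold changes were recovered in simulated data. The changed genes had a mean level of at least 50, so recovery at lower levels was not measured. The simulation gave all groups the same spread per gene, and depth was not varied on its own.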

Other observations

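Dilution of kidney CD4+ replicate 2 by other RNA, its genes left far below after removal of the length trend, the scatter of its T cell receptor signalling genes, and the correlation of those genes between libraries were tests chosen after the results were seen. The 12 genes for which DESeq2 found an organ difference that differed between CD8+ and CD4+ cells were chosen after their values were seen, and limma gave each an adjusted p of 0.999. Cish, a feedback inhibitor of cytokine signals, was at 1649 and 523 in kidney CD4+, 1243 and 1452 in kidney CD8+, 1295 and 731 in spleen CD4+ and 146 and 107 in spleen CD8+ cells (DESeq2 log2 difference 3.32, adjusted p = 0.0144). Litaf (2.29, adjusted p = 0.0144) and Qpct (4.38, adjusted p = 0.00979) had the same direction. Fcgrt, which encodes the neonatal Fc receptor, was at 634 and 814 in spleen CD8+ cells and between 20.5 and 111 in the other 6 libraries (-4.65, adjusted p = 0.00123). Tnfsf8 (-3.31, adjusted p = 0.00215) and Cx3cr1, a chemokine receptor of effector cells (-3.49, adjusted p = 0.0260), were also on that side. The others were 1810011H11Rik, Cd244, Dcaf4 and Map6 on the first side and Amigo3 and Ggt1 on the second.

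Gcg, the glucagon precursor gene, was at 217 and 286 in spleen CD4+ cells and 16.2 and 82.2 in kidney CD4+ cells, with 0 reads in all 4 CD8+ libraries, and was at least 212-fold lower in spleen CD8+ than in spleen CD4+ cells (limma adjusted p = 0.0189). The call was lost without kidney CD8+ replicate 1 or any 1 of the 4 spleen libraries (adjusted p up to 0.377, and 3.40e-07 to 0.377 over 23 alternatives). Lists of podocyte, endothelial, gamma delta T cell and platelet markers had 1, 2, 4 and 2 tested genes and the fibroblast list 0, too few to test.

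The low values of kidney CD4+ replicate 2, where 165 of 2604 well expressed genes lay far below the other 7 libraries, were weighed against 3 technical explanations. A length trend as the whole cause left a median gap of 1.86 on the log2 scale (95% bounds 1.81 to 1.92, from 2.43 before), between the limits set for it, and 60 genes lay far below afterwards, 57 of them among the 156 members with a known length, against 5 in the next library, which argues against it as the whole cause but not against a part. Dilution by RNA of other cells would lower T cell receptor signalling genes alike, and while only 23.8% of 21 lay above the mean of the other libraries, short of the limit set, their differences ran from -3.17 to 0.92 with an SD of 1.11 against 0.716 in the next library, which argues against dilution as the whole cause. The first readouts, the median gap and the share above the mean, decided neither question. Both conclusions rest on the count of genes left far below and on the SD, whose limits were set after the results were seen. Too few cells would spare abundant transcripts, but the share of genes far below was 1.30 times as high above a log2 level of 11 as between 8 and 9 (7.33% against 5.65%). What set this library apart stays open, and no biological explanation was tested.

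Tubule transcripts in the 4 kidney libraries and neutrophil and erythroid transcripts in the 4 spleen libraries were weighed as RNA of other cells. The sort for CD4+ or CD8+ T cells with high CD44 was meant to remove such cells, but its purity is not shown here. The share of proximal tubule markers differed between replicates, with 0.0817% and 0.292% of reads in the kidney CD8+ libraries. For 22 neutrophil and erythroid markers the lowest of 6 correlations between spleen libraries, across markers that are not independent, was 0.883 (0.904 for neutrophil and 0.962 for erythroid markers alone), with Ngp at 1430 to 4114 over these libraries and Hba-a1 at 8750 ± 793 in spleen CD4+ cells. For 22 proximal tubule markers in the kidney libraries it was 0.693 (highest 0.924), and for distal nephron markers 0.571 (highest 0.883), which took 0.0181% and 0.126% of reads in the kidney CD4+ libraries. T cell receptor signalling genes, which T cells express, had a lowest correlation of 0.957 in spleen and 0.854 in kidney, so steady ratios of transcripts do not separate RNA of other cells from expression in the sorted cells. The origins cannot be told apart by this test, and a difference between T cells of the 2 organs stays open, untested.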
